A study of Arabidopsis thaliana with 4 samples.

How the data were processed

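Total RNA from leaves of 3 pooled plants per sample was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the file headers. For each spot the deposited scanner files hold a processed intensity, which per the file headers is background-subtracted, median spot and background intensities, and flags for outliers, saturation and signal well above background. These intensities were not normalized between arrays. A deposited table of the authors' log2 values for the same 4 arrays was also used. Its scale and centring are not stated, and the differences between arrays in it matched those recomputed from the processed signals, after scaling to the 75th percentile, with a correlation of 1.00 over the 43603 gene probes. Its column medians were 0.051 and 0.018 for control replicates 1 and 2 and -0.050 and -0.018 for inoculated replicates 1 and 2. The authors' log2 values had a probe-wise centre removed, so they show differences between arrays and not levels.

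Samples were grouped by the labels as control (2 samples) and inoculated (2 samples). The labels give no replicate numbers, so replicates are numbered in deposition order, and they do not say whether the samples came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. All 4 arrays came from 1 slide and 1 scan, so no batch of slide or scan could be tested. Position on the slide and group cannot be told apart.

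Control spots and outlier-flagged spots were left out, 6 to 16 gene spots per array being flagged, and 23 probes without a usable spot on some array were dropped. The log2 processed signals of the spots of a probe were averaged, and the 75th percentile of each array was subtracted. A probe was tested if it was well above background on both arrays of at least 1 group, which held for 31818 probes. The accession of a probe was matched without its version to the RefSeq table of assembly TAIR10.1. Of 43603 probes, 34348 matched a locus, and 25410 loci were covered. The table served for names only, and no coordinates are given, because the array design names its build differently. Unmatched probes kept the name in the file and were tested under it as genes of their own. Of the 23782 genes tested, 19741 had a locus. A gene was represented by its brightest tested probe, judged over all 4 arrays, and 6185 of the 23782 genes tested had several. Where a group was not well above background on both arrays, the fold is given as a bound. It applies to the processed signals only, and another background correction can give a lower fold. The bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the lowest signal well above background and the probe's own signal. That lowest signal is no detection limit, because probes not well above background can lie above it. Folds given below as "at least" use this bound and are therefore not strict lower limits.

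Inoculated and control samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, called at an adjusted p under 0.05). Standard errors are those of the moderated fit. Gene lists on hormones, defence, metabolism, nutrients, stress, the clock and other organs, 34 in all, were fixed before the data were examined. The 33 with at least 5 tested genes were compared with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run beside it. The seed storage list had 1 tested gene and was not compared. The number of genes past 0.05 adjusted over the list alone was counted for each list, with no further correction over the 34 lists.

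Named genes were chosen by a rule fixed before the data were examined. It takes the 10 genes with the largest rise and the 10 with the largest fall among genes that pass and whose groups do not overlap. Where too few pass, it fills up with the smallest p among genes with an absolute log2 fold change of at least 1. Only genes with a locus and groups that do not overlap were taken in this step. It further takes the 4 genes with the smallest p of each list that camera called. The same holds for the salicylic acid, jasmonate, ethylene, pattern-triggered immunity and strigolactone lists. Counts of 5 or fewer could be named in full, but not all were.

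The steps were tested on simulated data drawn with the variance of these arrays, with 200 of 23782 genes changed in each of 20 runs. Of genes changed by 1 on the log2 scale 0.90% were called, of those changed by 2 64.1%, by 3 86.4% and by 4 94.6%. Of 100 simulated unchanged lists of 20 independent genes, camera with the preset correlation gave an unadjusted p under 0.05 for 5%. With a correlation of 0.3 between the genes of a list it did so for 40% of 100 lists, against 2% with an estimated correlation. For the lists of independent genes the estimated correlation gave 0%. For 100 lists of independent genes shifted by 0.5 it gave 89%, against 100% with the preset correlation.

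Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, a 75th percentile over probes detected on all arrays, and the authors' deposited table. Further ones were no filter on dim probes, a filter on all 4 arrays, outlier spots kept, saturated probes left out, the mean of the probes of a gene, an intensity trend with robust variance, and an absolute log2 fold change of at least 1. An adjusted p under 0.10 and leaving out each array in turn completed them. Normexp used the median spot signals, because mean spot signals are not among the columns used here. Its offset is added to every signal and so lowers the folds of dim probes.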

Results

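Transcript levels were measured in shoots of Arabidopsis thaliana, a small flowering plant used as a model, with and without inoculation with a fungal endophyte of the genus Mucor, a fungus that lives inside plant tissue. Seedlings grew in vitro, were inoculated 10 days after germination and were harvested 5 days later, at an age of 15 days. Each sample pooled the leaves of 3 plants. There were 2 control samples and 2 inoculated samples, each hybridised to its own 1-colour array, and all 4 arrays lay on 1 slide. The design addressed which shoot genes differ between inoculated and non-inoculated plants. Between 31421 and 32463 of the 43603 gene probes were well above background on each array, and no gene spot was saturated. The number of arrays limits the precision. Across the 23782 genes tested, the SD of the log2 difference was 0.44 between the 2 control arrays and 0.45 between the 2 inoculated arrays. It lay between 0.46 and 0.53 for the 4 pairs of a control and an inoculated array. These SDs are across genes, which are not independent replicates.

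Inoculated shoots held more transcript of BAM5, a beta-amylase, and of DIN2, a beta-glucosidase known for its induction in darkness, than either control sample. BAM5 was 8.45-fold higher (log2 fold change 3.08, SE 0.39, n = 2 per group) and DIN2 was 4.77-fold higher (2.25, SE 0.29). The cytokinin response regulator ARR15 was 2.11-fold higher (1.08, SE 0.14), while the cytokinin list that holds it had a median log2 fold change of -0.0028 over 15 genes. LTI30, a dehydrin of cold and drought responses, had a log2 fold change of -1.60 (SE 0.21), and IGMT5, a methyltransferase of indole glucosinolate synthesis, one of -1.17 (SE 0.19). None of the 23782 genes passed an adjusted p of 0.05 in limma.

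These 5 genes passed 0.05 when adjusted over the list alone, that is, over the fixed gene list that holds them. Across the 34 lists, 8 genes on 7 lists did so, and 0 of the same 8 genes passed when adjusted over all genes tested. The other 2 splits of the 4 arrays into pairs, each mixing control with inoculated, gave 10 and 22 such genes. BAM5 had an adjusted p of 0.016 over the list of sugar transport and carbon use, against 0.20 over all genes. For DIN2 the adjusted p was 0.0058 over the leaf senescence list, and for ARR15 it was 0.013 over the cytokinin list, each against 0.20 over all genes. LTI30 had 0.025 over the abscisic acid list against 0.21 over all genes, and IGMT5 had 0.045 over its list against 0.26. The other 3 genes were not well above background on either control array. Only the bound of the fold on the processed signals, which is not a strict lower limit, can therefore be given. PRR9, a pseudo-response regulator of the circadian clock, was at least 3.36-fold higher in inoculated shoots on these signals (adjusted p = 0.010 over its list alone, 0.19 over all genes). SAG12, a cysteine protease of senescing leaves, was at least 1.8-fold higher (0.0058 over its list alone, 0.19 over all genes). BHLH100, a transcription factor of the iron deficiency response, was at least 1.17-fold higher (0.0048 over its list alone, 0.17 over all genes). DIN2 passed over its list in every alternative fit run. SAG12, BHLH100 and PRR9 did not pass with normexp background correction, under which PRR9 was 1.49-fold higher, and could not be tested among probes above background on all 4 arrays. BAM5 did not pass when control replicate 1 or 2 was left out, and ARR15 did not pass when any of the 4 was. LTI30 and IGMT5 did not pass without control replicate 1, inoculated replicate 1 or inoculated replicate 2. IGMT5 and LTI30 did not pass with no filter on dim probes, nor IGMT5 with quantile normalization, median scaling or the mean of its probes. PRR9 also did not pass without inoculated replicate 1. With 1 replicate left out, 11 to 20 genes passed over their lists, among them 4 of these 8 without control replicate 1, 6 without control replicate 2, 4 without inoculated replicate 1 and 5 without inoculated replicate 2.

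**Figure D1:**
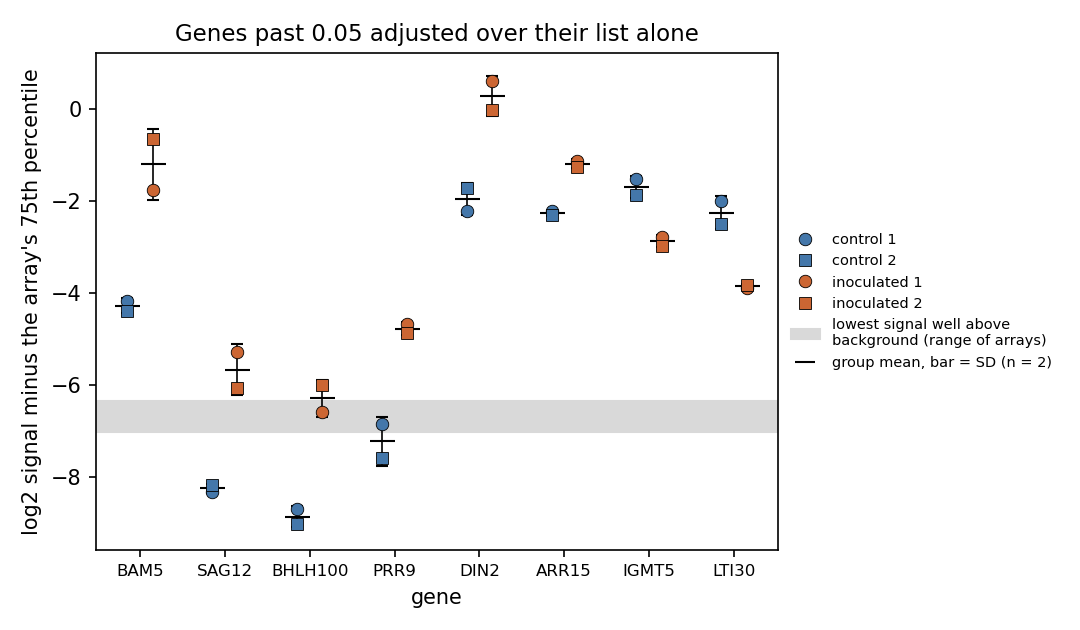
Signal of the 8 genes past 0.05 adjusted over their list alone, as log2 signal minus the array's 75th percentile (vertical axis), for each of the 4 arrays (points), with group means and SD bars (n = 2). The 2 inoculated arrays lie on the same side of both control arrays for each gene, and the control points of SAG12, BHLH100 and PRR9 lie below the grey band, the range over the arrays of the lowest signal well above background, or reach its lower part.

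Over all genes, limma called 0 genes higher and 0 lower, and the smallest adjusted p was 0.13. At an unadjusted p under 0.05 there were 1915 genes, 707 higher and 1208 lower in inoculated shoots, where chance alone gives about 1189. The share of lower genes among them was 63.1%, but 48.1% of 2065 genes with quantile normalization and 47.2% of 2540 genes without inoculated replicate 1. A difference of at least 2-fold was seen for 631 genes, of which 167 were higher and 464 lower. These counts were 32 higher and 125 lower with normexp background correction, 66 and 332 among probes above background on all 4 arrays, and 475 and 1437 with no filter on dim probes. They were 259 and 934 without control replicate 1, 261 and 1016 without control replicate 2, 532 and 710 without inoculated replicate 1, and 564 and 565 without inoculated replicate 2, where the excess of lower genes was lost. Both inoculated arrays lay above both control arrays for 4803 genes and below them for 4630, together 39.7% of the genes, where chance gives 33.3%. Without control replicate 1, 0 genes were called higher and 67 lower, and without control replicate 2, 1 was called higher and 90 lower. Of these 67 and 91 genes, 65 and 87 were not well above background on either inoculated array, and 3 genes were called in both cases.

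Since no gene passed, the rule fixed beforehand gives the genes with the smallest limma p and an absolute log2 fold change of at least 1. Only genes with a locus were taken, and none of them passed the test. Their adjusted p over all genes lay between 0.13 and 0.17. Among those lower in inoculated shoots and well above background on all 4 arrays, LAC3, a laccase, had a log2 fold change of -1.74 (SE 0.14, n = 2 per group). The drought-repressed gene DR4 had -1.80 (SE 0.15), and TDR1, the transcription factor also called ERF98, had -1.67 (SE 0.14). AHL19, an AT-hook DNA-binding protein, had -1.68 (SE 0.14), the cytochrome P450 gene CYP78A8 -1.57 (SE 0.14) and AT3G50300 -1.73 (SE 0.16). Another 4 genes were not well above background on the inoculated arrays, so only bounds on the processed signals are given. Of these, AT5G05220 was at least 9.94-fold lower, the Clp family gene CLPB2 at least 6.32-fold, the acyl-lipid thioesterase gene AT1G35250 at least 3.52-fold and AT5G55360 at least 3.21-fold. On inoculated replicate 1, CLPB2 (-6.88) and AT1G35250 (-6.84) lay above the lowest signal well above background (-7.02) without being well above background themselves. The bound of AT1G35250 is thus close to its plain fold of 3.56. AT5G55360 was among the genes called when either control array was left out. In those fits its own spread came only from its dim inoculated arrays, at -9.23 and -9.18, so these calls add no support. Its log2 fold change ran from -4.11 to -3.67 with 1 replicate left out. Over the alternatives that kept both control arrays its adjusted p was 0.093 to 0.36.

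Among the genes higher in inoculated shoots, AT2G07719 was above background on all arrays, with a log2 fold change of 2.55 (SE 0.20, n = 2 per group). The other 9 were not well above background on either control array, so only bounds on the processed signals are given. LCR29, a small cysteine-rich protein, was at least 5.90-fold higher, AT1G20180 at least 2.17-fold, AT4G09210 at least 1.71-fold and AT3G28750 at least 1.56-fold. AT2G03130 was at least 1.48-fold higher, AT1G70680 at least 1.28-fold and AT3G46680 at least 1.18-fold. No fold is given for AT1G67460, whose bound was under 1. BHLH100, described above, was the remaining gene.

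Camera with a preset inter-gene correlation of 0.01 called 8 of the 33 lists tested, 4 higher and 4 lower, while the other 2 splits of the arrays into pairs gave 14 and 19 calls. It called the pattern-triggered immunity list lower, with a median log2 fold change of -0.33 over 35 genes (adjusted p = 0.023, and adjusted p = 0.99 with an estimated correlation). Of its genes, 29 had a negative and 6 a positive log2 fold change, and 0 passed the gene test, also when adjusted over the list alone. The transcription factors WRKY18 (-0.72, SE 0.31) and WRKY33 (-0.55, SE 0.28), the flagellin receptor FLS2 (-0.33, SE 0.15) and LYM2 (-0.43, SE 0.22), a LysM protein, had its smallest p. The list of camalexin and indole glucosinolate synthesis was called lower too, with a median of -0.28 over 22 genes (adjusted p = 0.023, and adjusted p = 0.99 with an estimated correlation). Beside IGMT5, its genes with the smallest p were IGMT2 (-0.85, SE 0.20), CYP81F2 (-0.50, SE 0.27) and the sulfotransferase SOT16 (-0.30, SE 0.20), and 1 gene passed when adjusted over the list alone. The median of the camalexin list turned to 0.061 without control replicate 2, and over the replicates left out that of the immunity list ran from -0.50 to -0.082. Without control replicate 2, the camera adjusted p was 0.37 for the immunity list and 0.36 for the camalexin list. Without inoculated replicate 2 it was 0.85 and 0.28. Salicylic acid, camalexin and root genes were all highest on the array of control replicate 2, with list medians of 0.64, 0.48 and 0.64 above the mean of each gene over the arrays.

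The salicylic acid list had a median log2 fold change of -0.22, with 23 of 24 genes below 0. Camera did not call it (adjusted p = 0.064, and adjusted p = 0.99 with its estimated correlation of 0.79). The immunity repressors NIMIN1 (-1.17, SE 0.43), NIMIN2 (-0.63, SE 0.49), NPR3 (-0.33, SE 0.25) and the transcription factor WRKY38 (-0.43, SE 0.37) had its smallest p. With 1 replicate left out, NIMIN1 ran from -1.79 to -0.55 and NIMIN2 from -1.24 to -0.027, while WRKY38 turned to 0.076 without control replicate 2. The median of the list turned to 0.18 without control replicate 2. At the preset correlation, camera called the list lower with quantile normalization (adjusted p = 0.039). It also did so without control replicate 1 and without inoculated replicate 1. PR1, a marker of salicylic acid responses chosen after its values were seen, differed more between the 2 control arrays, at 2.05 and 4.15, than between the groups (-0.79, SE 0.72).

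Of the jasmonate genes, CORI3, a cystine lyase, had a log2 fold change of 0.996 (SE 0.19), while the signalling repressors JAZ7 (-0.87, SE 0.36) and JAZ1 (-0.65, SE 0.32) and the allene oxide cyclase AOC1 (-0.31, SE 0.13) were lower. The median of the 32 genes was -0.26 (camera adjusted p = 0.27), and it turned to 0.064 without control replicate 2. Among ethylene genes, the F-box gene EBF2 (-0.51, SE 0.15) and the response factors ERF6 (-0.59, SE 0.23) and ERF5 (-0.44, SE 0.19) were lower and HLS1 (0.44, SE 0.16) was higher, with a median of -0.08 over 26 genes (adjusted p = 0.22). The strigolactone synthesis genes CCD8 (1.48, SE 0.71), CCD7 (0.59, SE 0.31) and D27 (0.29, SE 0.16) were higher, and MAX1 (-0.23, SE 0.14) was lower. The value of CCD8 rests on the control arrays, which stood at -2.23 and -4.34, and was 2.53 without control replicate 1 and 0.42 without control replicate 2. The strigolactone list as a whole had a median of -0.03 and a mean of 0.09 over 16 genes. Camera, which takes its direction from the test statistics of the genes, gave higher (adjusted p = 0.96). The median of the strigolactone list ran from -0.19 to 0.15 with 1 replicate left out. Without control replicate 1, camera at the preset correlation called the jasmonate and ethylene lists lower and the strigolactone list higher. Without inoculated replicate 1 it called the ethylene list lower. On all 4 arrays with an estimated correlation, the camera adjusted p was 0.99 for each of the jasmonate, ethylene and strigolactone lists. No gene of these 4 hormone lists passed when adjusted over all genes or over the list alone.

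Camera called the clock list higher in inoculated shoots, with a median log2 fold change of 0.17 over 19 genes, 14 of them above 0 and 5 below (camera adjusted p = 0.025, and adjusted p = 0.99 with an estimated correlation). After PRR9, the genes with the smallest p were PRR7 (1.22, SE 0.35), LNK1 (0.77, SE 0.25) and LUX (0.48, SE 0.15), and PRR9 alone passed when adjusted over the list alone. The camera adjusted p was 0.19 without control replicate 2 and 0.42 without inoculated replicate 1, and 0.057 when only probes above background on all 4 arrays were kept. Genes of phenylpropanoid, flavonoid and anthocyanin synthesis were called higher, with a median of 0.26 over 22 genes, 20 of them above 0 (adjusted p = 0.023, and adjusted p = 0.99 with an estimated correlation). The activators MYB75 (0.82, SE 0.28) and MYB111 (0.52, SE 0.19) were higher and MYBL2 (-0.80, SE 0.42), a repressor of flavonoid synthesis, was lower. PAL1, the entry enzyme of the pathway, had 0.27 (SE 0.16), and 1 of its 2 probes went the opposite way. No gene of this list passed when adjusted over all genes or over the list alone. Without control replicate 2 the adjusted p of this list was 0.28, and without inoculated replicate 2 it was 0.81, with a median of -0.055.

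Guard cell and stomatal lineage genes were also called higher, with a median of 0.19 over 11 genes (camera adjusted p = 0.025, and adjusted p = 0.99 with an estimated correlation). MYB60 (0.47, SE 0.22), SPCH (0.41, SE 0.21), the potassium channel KAT1 (0.25, SE 0.14) and the kinase HT1 (0.33, SE 0.19) had the smallest p. Its adjusted p was 0.30 without control replicate 2 and 0.44 without inoculated replicate 2. The heat shock list, of which 6 of 12 genes could be tested, had a median of 0.67 (adjusted p = 0.023, and adjusted p = 0.99 with an estimated correlation). HSP101 (1.12, SE 0.36), HSFA2 (1.27, SE 0.51), HSP18.2 (0.39, SE 0.21) and MBF1C (0.43, SE 0.28) had the smallest p, and the list was highest on the array of inoculated replicate 1. With 1 replicate left out, HSFA2 ran from 0.65 to 1.88 and the median of the list from 0.17 to 1.99. Its adjusted p was 0.17 without control replicate 1 and 0.50 without inoculated replicate 1. Genes of zinc and copper homeostasis were called lower, with a median of -0.18 over 21 genes (adjusted p = 0.030, and adjusted p = 0.99 with an estimated correlation). The superoxide dismutases FSD1 (-0.50, SE 0.21) and CSD1 (-0.34, SE 0.17), the transporter ZIP5 (-0.52, SE 0.23) and the metallothionein MT2A (-0.53, SE 0.25) had the smallest p. This list lost its call without control replicate 1 (adjusted p = 0.069), without control replicate 2 (0.19) and without inoculated replicate 1 (0.053). It lost the call with quantile normalization too (0.057), and with no filter on dim probes (0.27), as did the immunity and camalexin lists (0.27 each). No gene of these 3 lists passed when adjusted over all genes or over the list alone.

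Root genes, fixed as markers of another organ, were called lower, with a median of -0.46 over 12 genes (camera adjusted p = 0.036, and adjusted p = 0.99 with an estimated correlation). The beta-glucosidase PYK10 (-0.72, SE 0.16), its binding protein PBP1 (-0.45, SE 0.13), the endodermal factor MYB36 (-0.68, SE 0.25) and PRP3 (-0.79, SE 0.38) were lower on both inoculated arrays than on either control array. No root gene passed when adjusted over all genes or over the list alone. The adjusted p was 0.33 without control replicate 2, 0.43 without inoculated replicate 1 and 0.063 with the mean of the probes of each gene. With fry, which asks whether the genes of a list move on balance in a single direction, 0 of 33 lists were called. Its test for change in either direction called the cytokinin list alone (adjusted p = 0.049). That list had 7 genes above 0 and 8 below, and camera did not call it (adjusted p = 0.52). Camera with an estimated correlation called 0 lists, so none of the 8 calls held under it. In simulation it gave an unadjusted p under 0.05 for 0% of unchanged lists of independent genes, so it was strict. For the zinc and copper list its unadjusted p was 0.096, against 0.0064 at the preset correlation, though the estimated correlation was -0.030. The lost calls alone therefore do not show that these lists were unchanged. In simulation the preset correlation gave an unadjusted p under 0.05 for 40% of unchanged lists whose genes had a correlation of 0.3. Of the 8 called lists, 7 had estimated correlations of 0.17 to 0.70, so their calls do not show a change either.

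**Figure D2:**
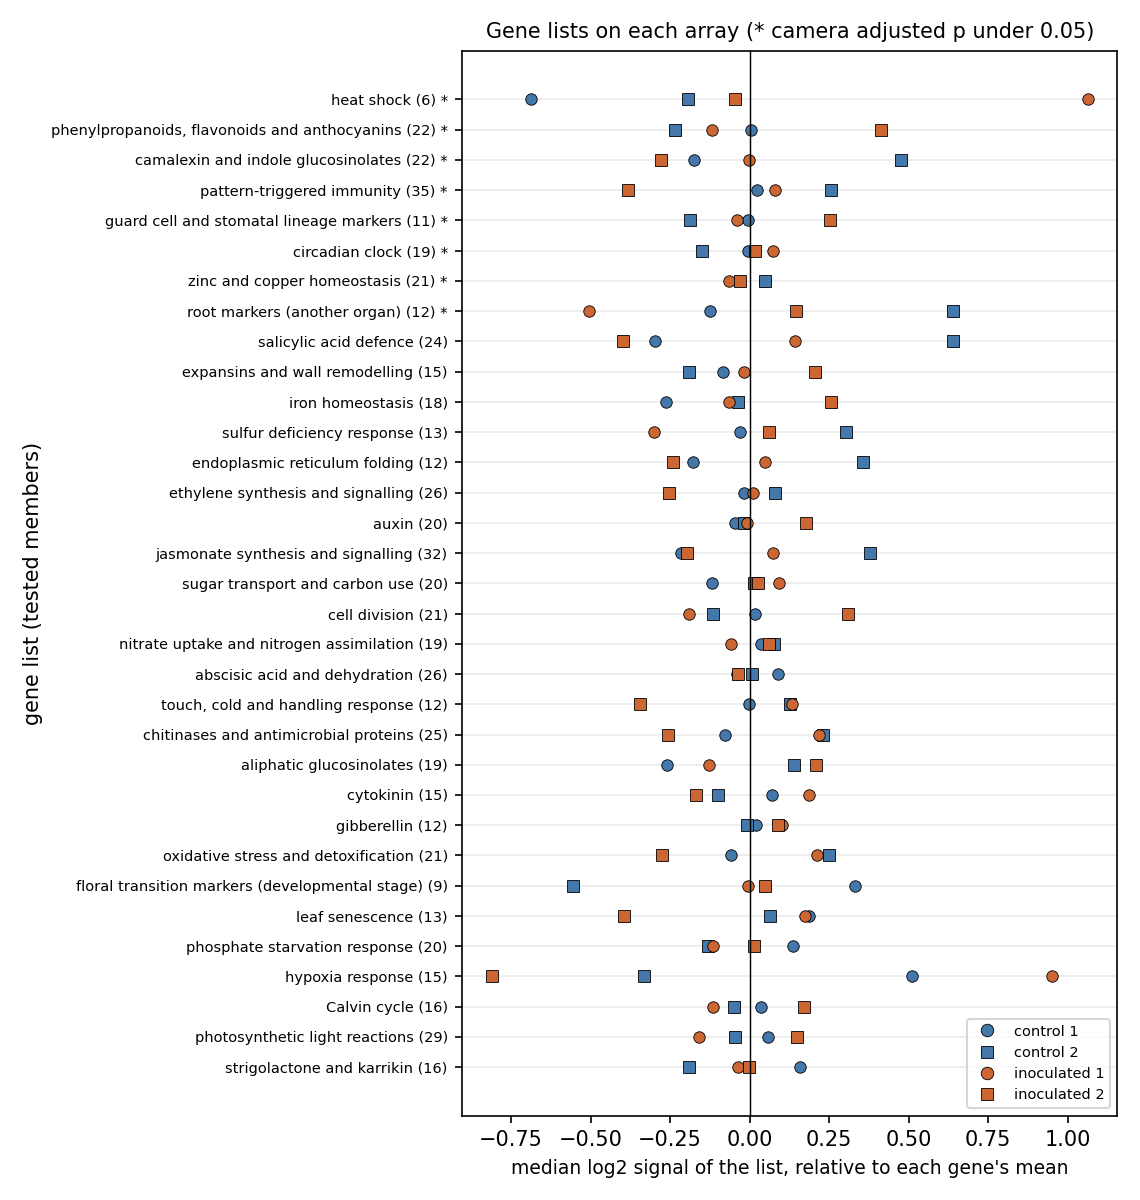
Median log2 signal of the tested genes of each of the 33 lists tested, relative to the mean of each gene over the 4 arrays (horizontal axis), with 1 point per array and the number of tested genes in brackets. Arrays of the same group often lie far apart, as for hypoxia genes, where inoculated replicates 1 and 2 stand at 0.95 and -0.81, and asterisks mark the 8 lists with a camera adjusted p under 0.05 at the preset correlation.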

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

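The counts at an unadjusted p and over the list alone were added under the alternatives after the data were seen. Leaving out saturated probes removed nothing, because no gene spot was saturated, and so tested nothing. In the other 10 alternatives that kept all 4 arrays, limma called 0 genes. Among them, the authors' table and the outlier spots kept nearly repeat the main values, with 1915 and 1914 genes at an unadjusted p under 0.05, and so test little. On the main values an adjusted p under 0.10, or an absolute log2 fold change of at least 1 as a further condition, gave 0 genes too, whereas an adjusted p under 0.10 gave 6 genes with quantile normalization and 1 with an intensity trend and robust variance. The smallest adjusted p lay between 0.079 and 0.36, and 1726 to 2410 genes had an unadjusted p under 0.05. With 1 replicate left out, when the lone sample is assumed to vary like the other group, 0 to 91 genes were called, 0 to 1 higher and 0 to 90 lower, and 1709 to 2540 had an unadjusted p under 0.05. The calls came without control replicate 1 (67) and without control replicate 2 (91). The share of lower genes at an unadjusted p under 0.05 was 63.1%, against 48.1% with quantile normalization.

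Over the list alone, 8 genes passed, 5 with the filter on all 4 arrays, under which 3 of them went untested, 11 with the mean of the probes of a gene, 12 with an intensity trend and robust variance, and 11 to 20 with 1 replicate left out.

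Camera called 8 lists, and 7 or 8 in the alternatives that kept all 4 arrays. It called 0 with an estimated correlation, as did fry, and 2 to 15 with 1 replicate left out. Without control replicate 1, 6 of the 8 lists were still called, without control replicate 2 only heat shock, and 4 without inoculated replicate 1 or 2. Over the replicates left out, the adjusted p of the 8 lists lay between 9.6e-17 and 0.85. With quantile normalization the salicylic acid list was called lower (adjusted p = 0.039, against 8.2e-09 to 0.94 over its other alternatives with camera at the preset correlation). Direction, as camera gives it or as the sign of the median, turned in some cases, and the cause was not tested. With 1 replicate left out, list medians ran from -0.79 to 0.18 for salicylic acid, -0.45 to 0.064 for jasmonate, -0.24 to -0.016 for ethylene, -0.79 to 0.061 for camalexin and -0.19 to 0.15 for strigolactone. They ran from -0.055 to 0.54 for phenylpropanoids, 0.17 to 1.99 for heat shock, -0.96 to -0.050 for root markers, -0.50 to -0.082 for pattern-triggered immunity, 0.050 to 0.25 for the clock, 0.061 to 0.33 for guard cells and -0.23 to -0.17 for zinc and copper. Camera or fry turned the strigolactone list also with quantile normalization (median 0.0019), the mean of the probes of a gene (-0.053) and fry (-0.027). WRKY38 ran from -0.93 to 0.076 with 1 replicate left out. The filter on all 4 arrays left 15 named genes untested.

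No paired analysis was possible because the labels give no replicate numbers. Signal over background limits the genes not well above background in a group to bounds.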

Other observations

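Tests of other splits of the arrays for gene and list calls, except those over the list alone, of inter-gene correlation and of the dimness of clock probes were chosen after the results were seen.

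Several gene groups differed more between arrays of the same group than between the groups. Hypoxia genes, named here after their values were seen, were high on the array of inoculated replicate 1 and low on that of inoculated replicate 2, with list medians of 0.95 and -0.81 relative to the mean of each gene. The alcohol dehydrogenase ADH1 stood at 4.56 and 2.15 on these arrays and at 3.32 and 2.49 on the control arrays (log2 signal minus the 75th percentile). Floral transition genes had medians of 0.33 and -0.56 on control replicates 1 and 2, and the floral organ gene AP3 stood at -3.12 and -4.48 there. The leaf senescence list had a median log2 fold change of -0.25 and a mean of 0.39. Camera takes its direction from the test statistics of the genes, not from either value, and gave lower (adjusted p = 0.76). SAG29 (at least 8.68-fold, well above background on 1 of the 2 control arrays), SAG12 and DIN2 were higher in inoculated shoots, whereas ORE1 (-0.82, SE 0.29), SAG21 (-0.63, SE 0.23) and WRKY6 (-0.70, SE 0.26) were lower on both inoculated arrays than on either control array. None of them passed an adjusted p of 0.05 over all genes in limma.

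Of the 18 iron homeostasis genes tested, 11 had a positive and 7 a negative log2 fold change, with a median of 0.31 (camera adjusted p = 0.14, and adjusted p = 0.99 with an estimated correlation). BTS had 0.53 (SE 0.15) and the ferritin FER4 -0.37 (SE 0.18), and BHLH100 alone passed when adjusted over the list alone. Genes of the photosynthetic light reactions and of the Calvin cycle had medians of -0.0035 and 0.07 (adjusted p = 0.96 and 0.88).

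The first pattern weighed is the 8 list calls at the preset correlation. All 3 of the 3 splits of the arrays into pairs, too few for a share under 0.05, called at least 8 lists, the highest other count being 19. At an unadjusted p under 0.05, 1 of the 3 splits, the real one, gave as many as 1915 genes, and the highest other gave 1346, whereas 3 of the 3 gave at least 8 genes past 0.05 over the list alone, the highest other 22. For 7 of the lists, the explanation that genes of a list vary together between arrays of a group is consistent with a median estimated correlation of 0.52 (0.17 to 0.70). For the zinc and copper list the estimated correlation was -0.030, which gives no sign of such shared variation. That estimate rests on few arrays, and its accuracy was not tested, so the explanation stays open for this list.

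The second is the higher signal of PRR9 and PRR7, clock genes expressed during the day. PRR7 was well above background on all 4 arrays. For PRR9, inflation by dim control signal stays open, because its fold was at least 3.36 on the processed signals and 1.49 with normexp background correction. Harvest of inoculated shoots later after lights-on could give the same pattern, and was tested with 10 genes induced by light and 12 high in darkness, written down before their values were seen. The median log2 fold change of the light-induced genes exceeded that of the dark-induced genes by 0.21, and by -0.14 to 0.37 with 1 array left out, while on single arrays the difference was -0.35 and 0.24 for the controls and -0.0073 and 0.15 for the inoculated samples, control replicate 2 being above both. Only a later harvest was tested, and an earlier one was not. The genes used follow the change between darkness and light, so they may not separate times within the light period. Harvest time therefore stays open, as does an effect of inoculation, which was not tested apart from it.

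The third is that 464 of the 631 genes with a 2-fold difference were lower in inoculated shoots, 73.5%. Signal near background as the whole cause is argued against, because in the brighter part of the genes, those above the median level, 39 of 52 such genes, 75%, were lower (95% exact binomial interval 61.1% to 86.0%, which treats genes as independent). Only these 52 of the 631 genes lay in the brighter part, so for the dimmer ones signal near background stays open. The share in the brighter part was not recomputed with 1 replicate left out, so it may rest on a single array. Array scaling stays open, because the share was 61.4% with quantile normalization, the lowest of the scalings tested. With 1 replicate left out the share was 50.0% without inoculated replicate 2, with 564 genes higher and 565 lower, 57.2% without inoculated replicate 1, with 532 higher and 710 lower, and 78.3% and 79.6% without control replicates 1 and 2. An effect of inoculation on these genes stays open and was not tested apart from array scaling.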
